A study of Gallus gallus with 7 samples.

How the data were processed

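Single-nucleus RNA-seq was run on chick intestine lying before the umbilicus, dissected from wild-type embryos at embryonic day 5 (E5), E6 and E7 and kept frozen before nuclei were released by Dounce homogenisation. Per the labels, which name no sort, nuclei were encapsulated in 10x Genomics 3' version 3.1 droplets, in which a barcode marks the droplet and a unique molecular identifier (UMI) marks the captured transcript. The labels list 7 libraries: 3 at E5, 3 at E6 and 1 at E7. Count matrices of 4 libraries were analysed here, E5 replicate 1, E5 replicate 3, E6 replicate 3 and E7 replicate 1. Of E5 replicate 2, E6 replicate 1 and E6 replicate 2, only the barcodes and gene lists were used, for the number of nuclei. No label said whether replicates came from separate embryos, pools or dissections, so p-values measure only the spread between these libraries, which may be technical.

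The deposited values were raw UMI counts per gene and barcode, made by the authors with Cell Ranger against the GRCg7b build, per the submitters' processing notes; the Cell Ranger version was not given in the sources used here. Every barcode held 500 UMIs or more, so any shallower nucleus was absent before the present work began. The gene annotation differed between libraries: the E5 and E6 matrices listed 25486 features under NCBI names, and the E7 matrix listed 30108 features under Ensembl identifiers and names. Libraries were joined by gene symbol, which left 12745 shared genes that held 75.2, 74.1, 75.4 and 78.8% of the UMIs of E5 replicate 1, E5 replicate 3, E6 replicate 3 and E7 replicate 1. Of these, 11052 reached 1 CPM (UMIs of a gene scaled to a common total) over all nuclei of every library. A different annotation assigns reads to different gene models, so gene values at E7 against E5 or E6 carry the annotation as well as the age. Comparisons within libraries do not. The E5 and E6 libraries were counted on the same annotation. Their main fits were still limited to the shared genes and also held the E7 library, so counts of genes past the threshold at E6 depend on both. FRMD8 alone took 11.5, 13.2 and 12.4% of UMIs in the E5 and E6 libraries and was not among the shared genes.

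Nuclei with more than 5% mitochondrial UMIs were removed. Doublets were simulated within each library by adding random pairs of nuclei, and nuclei whose score over 40 neighbours exceeded 0.7 were treated as doublet-like and removed. These were 15.9, 17.0, 13.0 and 11.5% of the nuclei of the 4 libraries in the order above, and 12709, 18042, 11708 and 11798 nuclei were kept. A score threshold of 0.8 had been written first and was lowered to 0.7 after the distribution of the scores had been seen; 0.8 was run as an alternative. Expression of 2000 variable genes was centred and scaled within each library, reduced to 30 principal components and clustered over 15 neighbours with the Leiden method at resolution 1. Genes of the fixed lists and genes of the W chromosome, 326 in all, took no part in clustering, and neither did mitochondrial genes. Other sex-linked genes were not left out as such. A cluster received a class name ending in "-like" when at least 3 markers of that class, fixed beforehand, were seen in 2% of its nuclei and 2-fold above the other clusters. The markers of that class also had to have the highest mean fold of all marker lists, above a minimum. No other list could have more members among the leading genes of the cluster, and shallow clusters with no marker there stayed unnamed. That naming rule was written after the first clusters had been seen. Unnamed clusters held 22.6, 23.7, 29.9 and 34.0% of the kept nuclei of the 4 libraries. Neuron-like nuclei were clustered again at resolution 0.5 over 20 components.

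Nuclei are not replicates, so raw counts were summed per library and class and the sums were tested with edgeR 4.0.16 (quasi-likelihood test, TMM normalisation, filterByExpr) in R 4.3.3, with Benjamini-Hochberg adjustment at 0.05. All 3 ages entered a shared fit, with contrasts of E6 and of E7 against E5. E6 and E7 had 1 library each, so the spread came from the E5 pair with 1 residual degree of freedom, moderated across genes, and the lone libraries were assumed to vary like E5. E7 was not tested against E6. Neuron-like and progenitor-like sums of the 4 libraries were compared with the library as a block. Class-relative changes were tested as the interaction of age and class with the library as a block. Shares of nuclei have exact Clopper-Pearson 95% intervals and no test, and intervals cover counting error only. For shares of nuclei with a UMI, each nucleus was thinned to 1000 UMIs and shallower nuclei were left out (10, 7, 21 and 13 neuron-like nuclei of the 4 libraries). Co-detection was measured as a log2 odds ratio per library with 0.5 added to each count, and tested over the 4 libraries by an exact two-sided sign-flip permutation test.

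The comparisons, the tests, the 18 gene lists, the cell type markers and the rule for named genes were fixed before the data were examined. The rule took from each list up to 4 members with the largest change past the threshold, or the 2 with the most counts, and the 8 largest rises and falls with 10 CPM or more that lay beyond both E5 libraries. Transmitter genes were named where the thinned share reached 5% in a library, together with NOS1, VIP, CHAT, TH and DBH. The rule gave more genes than are named below, and the choice among them was made after their values had been seen. Alternatives were another normalisation (RLE), DESeq2 1.42.0, no filter beyond 1 count, doublet-like nuclei kept, a resolution 2 times as high, no centring within libraries, a minimum of 1000 UMIs, thinning to 2000 UMIs or none, embryonic day as a linear trend, no library block between classes, and each library left out in turn. Chosen after the data were seen were the fits on libraries of 1 annotation, on genes seen in every library, at the first doublet threshold and without neuron-like subcluster 7. One test in the closing part was also altered after its first result: the ratio of posterior HOX genes was first taken over 10 measured genes and then over the 8 left when the pair that had drawn attention was removed, with a stricter reading, and both values are given there.

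The main edgeR tests were tested on simulated counts drawn from the means and depths of the real sums, with 200 genes or fewer changed by known folds. The class-relative tests of epithelium-like and smooth muscle-like nuclei, DESeq2 and the co-detection test were not simulated. All genes of a fit were drawn with a common dispersion, also in the lone E6 and E7 libraries, so a different spread in those was not simulated. For E6 against E5 in neuron-like nuclei, 0, 22.7 and 72.3% of genes changed 1.5-, 2- and 4-fold were recovered, over 9056 genes. For E6 against E5 in progenitor-like nuclei these shares were 9.52, 47.8 and 93.8% over 9636 genes. For neuron-like against progenitor-like sums they were 40.9, 90.8 and 100% over 8953 genes. Other software was Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, scikit-learn 1.9.0 and leidenalg 0.10.2. Some measured genes are not reported here and were left out of the counts of named genes.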

Results

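The series followed the intestine before the umbilicus over the days when enteric neuron subtypes first appear in the chick, and asked which neuronal genes and subtypes emerge between E5 and E7. The 7 libraries held 140054 barcodes: 15457, 23506 and 22252 in E5 replicates 1 to 3, 24484, 26822 and 13618 in E6 replicates 1 to 3, and 13915 at E7. Pairs of libraries shared 49 to 181 barcodes, against 51.5 to 178 by chance from a barcode pool that was estimated from the pairs of different ages, so the overall level of sharing was not tested. The 4 libraries analysed for expression held 35241010 UMIs (E5 replicate 1), 75135350 UMIs (E5 replicate 3), 38356575 UMIs (E6 replicate 3) and 53291709 UMIs (E7 replicate 1). Their median depths were 1765, 2689, 2222 and 3223 UMIs per nucleus. E6 and E7 values come from 1 library each and have no replicate of their own.

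The enteric nervous system (ENS) made up a larger part of the nuclei at E6 and E7 than in either E5 library. ENS-like nuclei, the neuron-like and progenitor/glia-like classes together, were 5.94% ± 0.18 (SD, n = 2) of kept nuclei at E5, 10.1% at E6 (95% interval 9.53 to 10.6%) and 14.99% at E7 (14.3 to 15.6%). Neuron-like nuclei were 2.23 and 1.73% in E5 replicates 1 and 3, 4.35% at E6 and 7.30% at E7. Progenitor-like nuclei were 3.85 and 4.08% at E5, 5.72% at E6 and 7.69% at E7. Within the ENS, neuron-like nuclei were 36.7 and 29.8% at E5, 43.2% at E6 (40.3 to 46.1%) and 48.7% at E7 (46.3 to 51.1%). The E6 and E7 shares of kept nuclei for these classes lay outside the E5 range by more than the gap between the E5 libraries, and so did the neuron-like share of the ENS at E7, while at E6 that share lay above the higher E5 library by less than the gap. Shares were not tested between ages. All nuclei had 500 UMIs or more and median depth ran from 1765 to 3223 UMIs, and both can set such shares. No label gave the anterior limit of the dissection. An unnamed cluster led by GATA3, BARX1 and NKX2-5 held 0.73 and 0.04% of kept nuclei at E5, 5.34% at E6 and 2.28% at E7. A difference of dissection could therefore also set the ENS-like shares and was not separated from age. Smooth muscle-like nuclei were 28.7 and 31.4% at E5, 17.7% at E6 and 16.0% at E7, but at the first doublet threshold these were 11.7, 14.2, 10.6 and 14.4%, so no comparison is drawn for them.

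**Figure D1:**
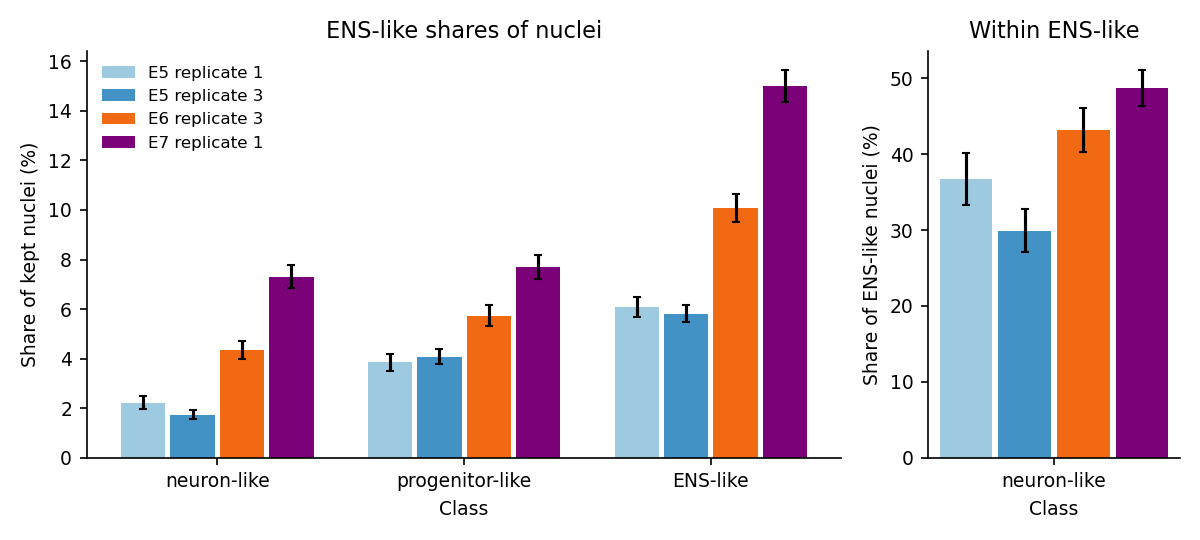
Share of kept nuclei (%) in the neuron-like and progenitor-like classes and in both together, and share of neuron-like among ENS-like nuclei (%), for the 4 libraries, with exact 95% intervals as error bars. ENS-like nuclei were 6.07 and 5.81% in the E5 libraries, 10.1% at E6 and 14.99% at E7.

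Neuron-like nuclei differed from progenitor-like nuclei of the same libraries in transmitter genes, channels, synaptic genes and cell cycle genes. CHAT, the enzyme that makes acetylcholine, was higher in neuron-like nuclei by 7.51 ± 0.23 on the log2 scale (edgeR, adjusted p = 2.51e-08, higher in 4 of 4 libraries). SLC5A7, the choline transporter, was higher by 7.42 ± 0.27. NOS1, the neuronal nitric oxide synthase, was higher by 4.94 ± 0.28, GAL (galanin) by 4.94 ± 0.32, VIP (vasoactive intestinal peptide) by 4.78 ± 0.31 and PENK (proenkephalin) by 3.70 ± 0.21. DBH, the enzyme that makes noradrenaline, was higher by 6.99 ± 0.36, at 78.1 CPM against 0.33 CPM. The progenitor-like value rests on few counts, so the size of this difference is not exact. Among neuron-like subclusters DBH was at 379 ± 126 CPM in subcluster 7 and at 48.7 CPM or less in every other. All 26 measured cell cycle genes were lower in neuron-like nuclei, among them CENPE (-1.91 ± 0.17) and BRCA1 (-2.17 ± 0.15).

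By list, all 6 measured inhibitory motor neuron genes and all 7 cholinergic genes were higher in neuron-like nuclei. Of 14 voltage-gated channel genes 13 were higher and 0 lower by edgeR, among them the calcium channel CACNA1E (5.21 ± 0.21). Of 19 synapse genes 16 were higher and 1 lower, with the presynaptic scaffold PCLO at 6.78 ± 0.23. Of 23 axon guidance and adhesion genes 17 were higher and 2 lower, with the netrin receptor UNC5C at 3.53 ± 0.17. Of 24 subtype transcription factors 16 were higher and 4 lower, and of 12 receptors 8 were higher and 1 lower. Of 6 catecholamine and serotonin genes 4 were higher, and of 3 excitatory and sensory peptide genes 2 were higher and 1, CALCA, lower (-1.16 ± 0.17), though its share of neuron-like nuclei did not exceed that of mesenchyme-like nuclei. Of 7 glia maturation genes 6 were lower, with the Notch target HES5 at -3.61 ± 0.34. Of 20 extracellular matrix genes 12 were lower and 3 higher, with tenascin TNC at -2.62 ± 0.17. Of 22 morphogen signalling genes 8 were higher and 3 lower, and of 11 RET and endothelin genes 2 were higher and 3 lower. Of 15 homeobox position genes 11 were higher and 1 lower, and HOXB6 (1.91 ± 0.22) was the opposite, -0.35, without neuron-like subcluster 7. HOXA9 was at 264 ± 61.2 CPM in that subcluster and at 11.8 CPM or less in every other. The list was not counted without subcluster 7, so its 11 genes are not read as a difference of neuron-like nuclei in general. Of 9 epithelium maturation genes 2 were higher and 1 lower, and of 8 stress genes 1 was higher and 3 lower. Counts adjusted over the list alone were equal for the other lists; for extracellular matrix they were 3 higher and 13 lower, and for stress genes 2 higher and 3 lower. Over all 9114 genes tested, 2150 were higher and 2102 lower, and DESeq2 gave 1717 and 1422. Marker genes of either class were left out of these examples. Both classes were formed by clustering these same nuclei, and genes used for clustering could be among all those tested. The counts over all genes and the p-values therefore do not test whether the classes are separate.

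Between E5 and E6, VIP, GAL, the transcription factors DLX5 and BNC2 and the adhesion genes CNTN5, EPHA7 and NLGN1 rose in summed neuron-like nuclei. VIP, a relaxing peptide of inhibitory motor neurons, rose by 2.20 ± 0.28 on the log2 scale (edgeR, adjusted p = 0.0192), from 60.3 and 36.7 CPM in the E5 libraries to 213 CPM. GAL rose by 1.74 ± 0.19, from 267 and 218 to 804 CPM, and was at 5.04 and 2.59 CPM at E5 and 13.9 CPM at E6 in mesenchyme-like nuclei, with no excess of its change over theirs (-0.18 ± 0.31, adjusted p = 0.98). Background was not separated from expression at these low mesenchyme-like levels, so that contrast does not decide where the rise of GAL lay. The homeobox gene DLX5 rose by 2.87 ± 0.29 and the zinc finger gene BNC2 by 1.89 ± 0.27. The contactin CNTN5 rose by 2.26 ± 0.16, the ephrin receptor EPHA7 by 2.18 ± 0.28 and the synaptic adhesion gene NLGN1 by 2.12 ± 0.24. The RNA-editing family gene ADARB2 rose by 3.78 ± 0.40, CHODL by 3.99 ± 0.36, the cation channel TRPM3 by 2.98 ± 0.23, the vesicle priming gene UNC13C by 3.14 ± 0.47 and the serotonin receptor HTR1E by 3.24 ± 0.47. The kinesin KIF26B fell by 1.32 ± 0.21. NOX3 rose by 2.67 ± 0.26, but was -0.11 without subcluster 7, so its rise lay in the nuclei of that subcluster. Neuron-like nuclei fell into different subclusters at E5 and E6: subcluster 4, with BNC2 and TRPM3 among its leading genes, was 5.30 and 2.24% at E5 and 17.5% at E6, and subcluster 6, with GAL, DLX5, BNC2 and UNC13C, was 7.42 and 7.67% at E5 and 12.2% at E6. Subcluster 10, led by ADARB2, EPHA7 and NLGN1 among others, held 0 of 283 and 0 of 313 nuclei at E5 and 17 of 509 at E6. Within subclusters, VIP was at 68.3 and 113 CPM at E5 and 370 CPM at E6 in subcluster 1, whose share was lower at E6 (30.4 and 24.6 to 15.5%), and at 37.4 and 39.9 and 217 CPM in subcluster 2, so its rise was not one of shares alone. GAL in subcluster 6 was at 743 and 1394 CPM at E5 and 3642 CPM at E6. The profile of subcluster 6 differed in E5 replicate 3, with BNC2 at 335 CPM against 5948 CPM at E6, so its nuclei may not be alike. Levels within subclusters were not tested, and for the other genes shares and levels were not separated. A difference of dissection between the E5 and E6 libraries was not separated from age in any E6 value.

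Of 7 measured inhibitory motor neuron genes 2 rose past the threshold, and 3 when adjusted over the list alone. Of 8 cholinergic genes 0 passed by edgeR over all genes, and 6 rose when adjusted over the list alone; CHAT was at 1.18 ± 0.21 (adjusted p = 0.0714). Synapse genes gave 1 rise of 21 (7 over the list alone), axon guidance genes 2 rises of 23 (4 rises and 1 fall over the list alone) and subtype transcription factors 2 rises of 25 (2 rises and 1 fall over the list alone). Voltage-gated channels gave 0 of 16 (3 rises over the list alone), and receptors 0 of 15 (1 rise). Extracellular matrix genes gave 0 of 22 (3 falls), RET and endothelin genes 0 of 12 (1 fall) and morphogen genes 0 of 24 (1 fall). The peptide and calcium-binding list gave 0 of 4 (1 rise). The catecholamine (8 measured), glia maturation (7), cell cycle (24), epithelium maturation (10), homeobox (21) and stress (11) lists gave 0 by either adjustment; in each of the lists at 0 the tool was edgeR, which over all genes gave 892 at an unadjusted p under 0.05, and DESeq2 gave 22 genes past its threshold and 208 unadjusted. Over 9353 genes, 37 rose and 1 fell. This count was not stable: RLE normalisation gave 175 rises and 110 falls, the alternatives ranged from 22 to 299 genes, and the spread came from 1 residual degree of freedom. VIP, GAL, DLX5, CNTN5, EPHA7, NLGN1, CHODL and TRPM3 passed under all 9 alternatives with a test, BNC2, ADARB2 and NOX3 under 8 of 9, and KIF26B under 7 of 9. In the same nuclei the sum of 6 erythroid markers was 2091 and 752 CPM at E5 and 217 CPM at E6, that of smooth muscle markers 1212 and 1175 and 848 CPM, that of mesenchyme markers 918 and 673 and 484 CPM and that of interstitial cell of Cajal markers 220 and 205 and 99.0 CPM. KIF26B was at 2605 and 3723 CPM in mesenchyme-like nuclei at E5, and GCG, a hormone gene of the pancreas, was at 1.95, 0 and 86.4 CPM in neuron-like nuclei.

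**Figure D2:**
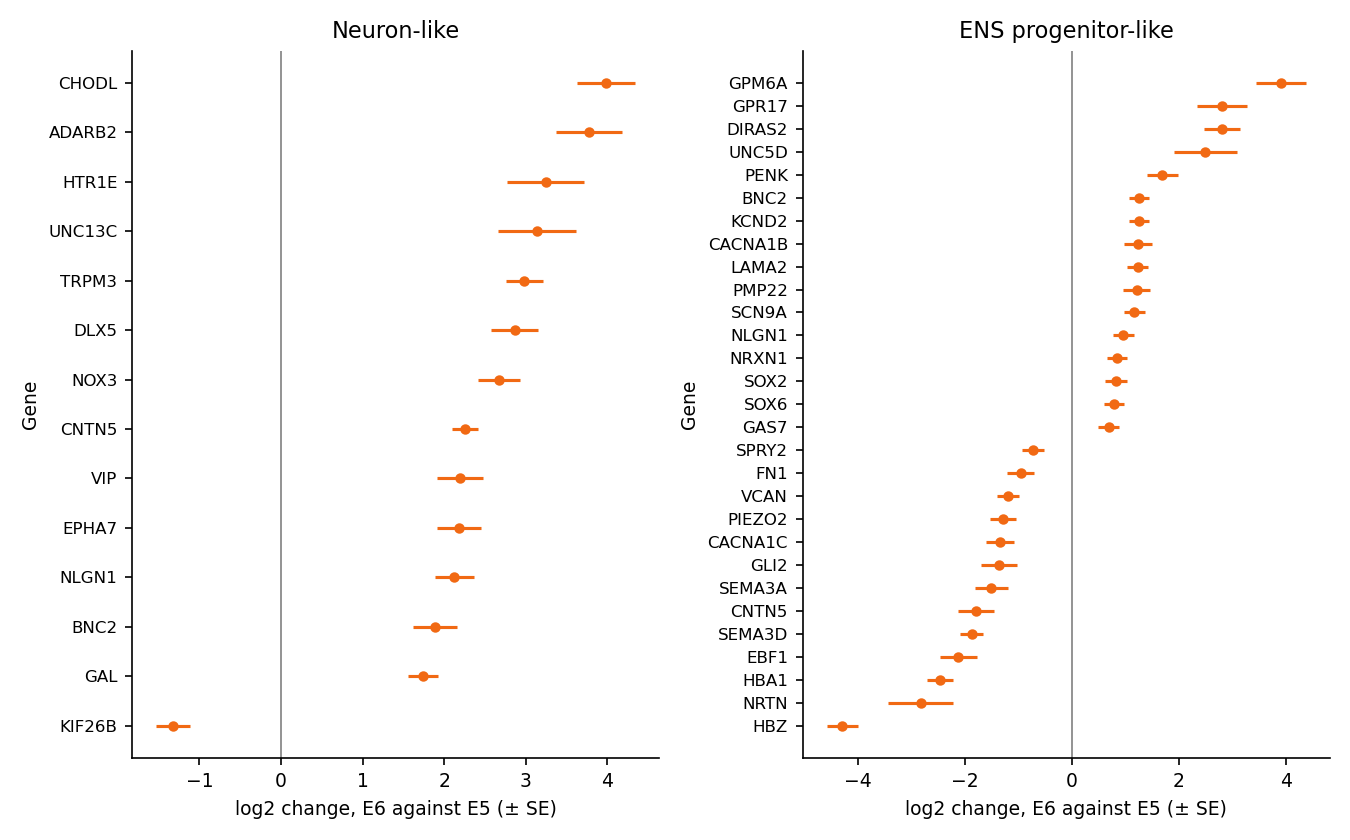
Change at E6 against E5 on the log2 scale with its standard error, for named genes past the threshold with more than 3 UMIs at E5 in neuron-like and ENS progenitor-like nuclei (edgeR, 2 E5 libraries and 1 E6 library). VIP in neuron-like nuclei was at 2.20 and SEMA3D in progenitor-like nuclei at -1.87.

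Between E5 and E7, in libraries counted on different annotations, VIP in neuron-like nuclei rose by 3.40 ± 0.26 (edgeR, adjusted p = 0.00017), to 490 CPM. The nicotinic receptor gene CHRNA7 rose by 1.76 ± 0.20, the tachykinin gene TAC1 by 2.73 ± 0.32, the vesicular acetylcholine transporter SLC18A3 by 1.22 ± 0.24 and CHAT by 0.86 ± 0.20. The mechanosensitive channel PIEZO2 rose by 1.78 ± 0.22, and CNTN5, EPHA7 and NLGN1 were again higher, by 2.37, 1.72 and 1.88. DBH fell by 1.43 ± 0.27, DDC, which makes dopamine and serotonin, fell by 1.03 ± 0.26, PROX1 fell by 3.27 ± 0.33 and the GDNF-family receptor GFRA3 fell by 2.44 ± 0.32. DBH and DDC were highest in subcluster 7 (379 ± 126 and 378 ± 138 CPM), which was 16.3 and 10.2% of neuron-like nuclei at E5 and 3.02% at E7. Without this subcluster DBH and DDC were at -0.39 and -0.17 and did not pass, PROX1 fell by 1.37 and GFRA3 did not reach the count filter. DBH and DDC passed under 6 of 9 alternatives each, CHAT and SLC18A3 under 7 of 9, and EPHA7 and NLGN1 under 8 of 9. DDC fell more in mesenchyme-like nuclei, and its change in neuron-like nuclei exceeded theirs by 1.58 ± 0.29 (edgeR, adjusted p = 5.88e-06). Set against mesenchyme-like nuclei, VIP (2.30 ± 0.29), PIEZO2, CNTN5, EPHA7, NLGN1, PROX1 and GFRA3 kept their direction and passed the threshold, and CHRNA7 (0.27 ± 0.26), TAC1, SLC18A3, CHAT and DBH did not pass. Of simulated 2-fold changes of this kind at E7, 19.7% were recovered, so not passing does not show that a change was shared by both classes. Cholinergic genes gave 3 rises and 1 fall of 8, inhibitory motor neuron genes 3 rises of 7, catecholamine and serotonin genes 3 falls of 8, and subtype transcription factors 2 rises and 7 falls of 25. One inhibitory motor neuron gene that rose was GUCY1A2, whose share of nuclei was below that in mesenchyme-like nuclei. Set against mesenchyme-like nuclei, edgeR gave for the same lists 0 of 8, 1 higher and 1 lower of 7, 2 higher and 0 lower of 11, and 2 higher and 5 lower of 26, among 1312 genes at an unadjusted p under 0.05. In all, 398 genes rose and 350 fell of 9353, and DESeq2 gave 99 and 133. Neither the annotation nor a difference of dissection could be separated from age in these values.

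The share of neuron-like nuclei with a transmitter transcript was compared at 1000 UMIs per nucleus. VIP was seen in 3.30 and 2.94% of neuron-like nuclei at E5, 9.84% at E6 (7.34 to 12.8%) and 21.7% at E7 (19.0 to 24.6%), against 0.715, 1.46, 1.56 and 2.03% of mesenchyme-like nuclei, which served as background. CHAT was seen in 7.69 and 8.50% at E5, 19.1% at E6 (15.7 to 22.8%) and 14.6% at E7 (12.3 to 17.2%). PENK was seen in 6.96 and 12.1% at E5, 23.6% at E6 (19.9 to 27.6%) and 14.99% at E7. GAL was seen in 16.5 and 11.4%, 28.3% and 20.5%, and SLC18A3 in 4.03 and 2.29%, 6.76% and 9.43%. NOS1 was seen in 3.66 and 5.88% at E5, 5.74% at E6 and 2.24% at E7, against 0.033 to 0.101% in mesenchyme-like nuclei. DBH was seen in 7.33 and 4.90% at E5, 1.64% at E6 (0.71 to 3.20%) and 2.24% at E7 (1.35 to 3.48%), and TH, the first enzyme of catecholamine synthesis, in 1.10, 0.654, 0.205 and 0.354%. DDC in neuron-like nuclei (10.3, 6.21, 4.51 and 3.42%) was above its mesenchyme-like share (5.04, 5.72, 3.96 and 1.31%) beyond counting error in E5 replicate 1 and at E7, and within it in the other libraries. GUCY1A2 and CALCA were below their mesenchyme-like shares in all 4 libraries, so they are not read as neuron-specific, and background was not separated from expression in both classes. Without thinning VIP was at 8.48, 5.75, 20.04 and 36.1%, with median depths of 2072, 3387, 2441 and 3422 UMIs in neuron-like and 1675, 2525, 1924 and 2882 UMIs in mesenchyme-like nuclei. Of 44 measured transmitter genes, 15 and 12 reached 5% at E5, 15 at E6 and 13 at E7. E7 shares also carry the change of annotation, and a difference of dissection was not separated from age at E6 or E7.

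**Figure D3:**
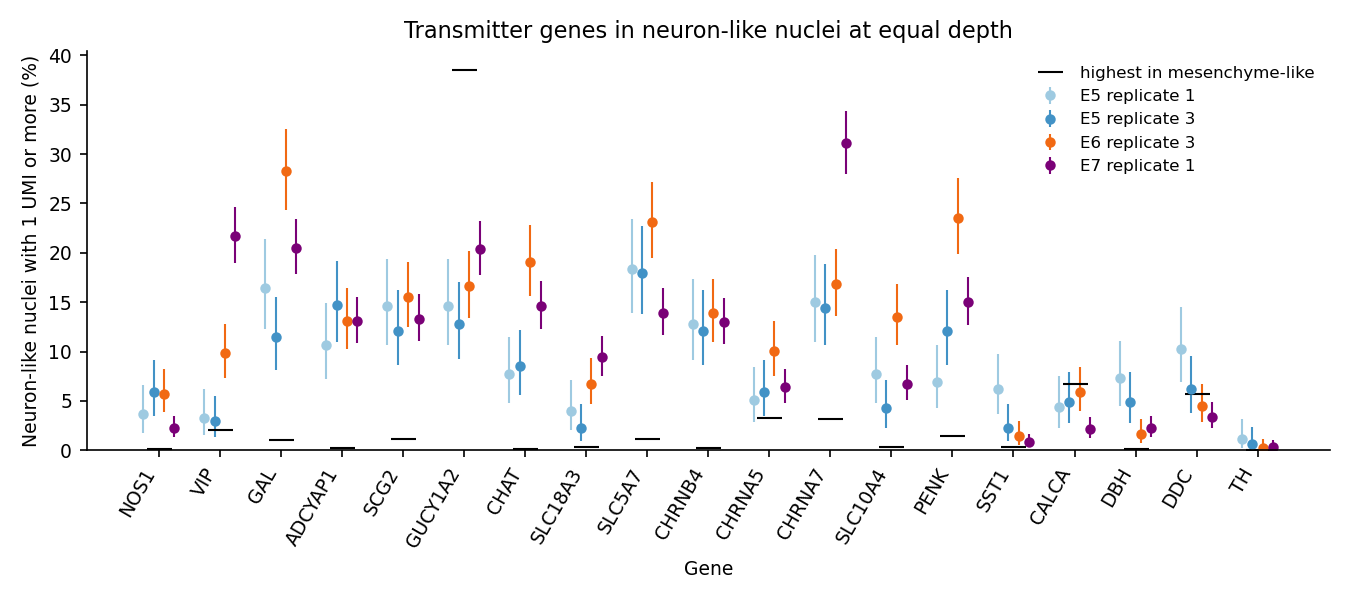
Share of neuron-like nuclei with 1 UMI or more (%) after thinning to 1000 UMIs, per gene and library, with exact 95% intervals; black dashes mark the highest share in mesenchyme-like nuclei. VIP was at 3.30 and 2.94% at E5, 9.84% at E6 and 21.7% at E7.

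Transmitter genes and subtype transcription factors fell into recurring combinations within neuron-like nuclei. NOS1 was seen together with TBX3 more often than separate occurrence gives (mean log2 odds ratio 2.09 ± 0.47, SD, n = 4) and with ETV1 (1.38 ± 0.69), and less often with CHAT (-1.95 ± 0.79), PENK (-1.96 ± 0.91) and SLC5A7 (-1.91 ± 0.71). NOS1 and VIP were seen together more often (2.15 ± 1.21), on 2, 1, 4 and 13 shared nuclei, but at 2000 UMIs this was 1.22 ± 1.49 and above 0 in 3 of 4 libraries. NOS1 and CHAT shared 0, 0, 1 and 0 nuclei. CHAT was seen with PENK (2.15 ± 0.86) and SLC18A3 (1.74 ± 0.33), and less often with ETV1 (-1.49 ± 0.51). GAL was seen with BNC2 (2.33 ± 0.39) and less often with TBX3 (-1.15 ± 0.16). BNC2 and TBX3 (-1.69 ± 0.23), and ETV1 and BNC2 (-1.51 ± 0.69), were seen together less often, while ETV1 and TBX3 went together (1.57 ± 0.32). Without subcluster 7, GAL with TBX3 was at -0.78 ± 0.72 and ETV1 with BNC2 at -1.22 ± 1.31, each above 0 in 1 of 4 libraries. Of 55 pairs of 11 genes, 15 were above 0 and 16 below 0 in all 4 libraries, where 6.88 are expected by chance. For each such pair the exact permutation p was the smallest that 4 libraries can give, which is above 0.05, and the adjusted p was 0.222. Without neuron-like subcluster 7, 11 of 45 pairs were above 0 and 8 below 0 in all 4 libraries, against 5.62 by chance.

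**Figure D4:**
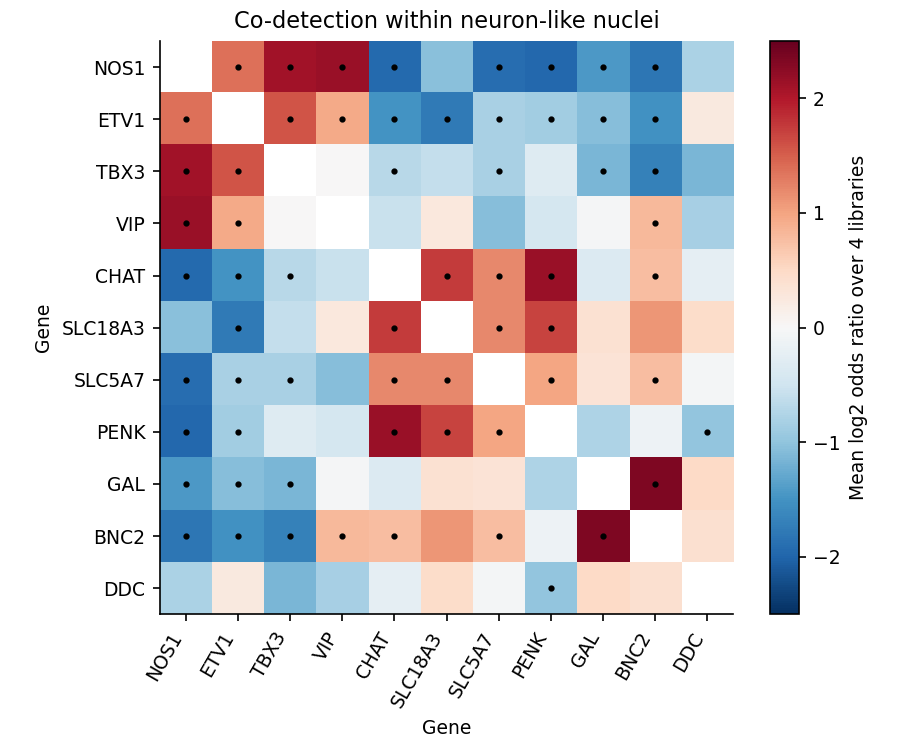
Mean log2 odds ratio of detection in the same neuron-like nucleus over 4 libraries, for pairs of 11 genes on both axes; black dots mark pairs with the same sign in all 4 libraries. GAL with BNC2 was at 2.33 and NOS1 with CHAT at -1.95.

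Between E5 and E6, SEMA3D, a secreted guidance protein, fell in progenitor-like nuclei by 1.87 ± 0.22 (edgeR, adjusted p = 5.84e-15), from 402 and 483 to 122 CPM. SCN9A and KCND2, voltage-gated sodium and potassium channels, rose by 1.16 ± 0.19 and 1.25 ± 0.19, and the calcium channel CACNA1B rose by 1.23 ± 0.26 while CACNA1C fell by 1.34 ± 0.26. PENK rose by 1.69 ± 0.29, BNC2 by 1.26 ± 0.19 and LAMA2, a laminin chain, by 1.23 ± 0.20. EBF1 fell by 2.12 ± 0.35 and PIEZO2 fell by 1.28 ± 0.24. The peripheral myelin gene PMP22 rose by 1.21 ± 0.25, SOX2 by 0.82 ± 0.21 and GPR17 by 2.80 ± 0.48, while the FGF feedback gene SPRY2 fell by 0.73 ± 0.20, versican VCAN fell by 1.20 ± 0.21 and fibronectin FN1 fell by 0.96 ± 0.25. SEMA3D, SCN9A, LAMA2 and VCAN passed under all 8 alternatives with a test, and PENK, CACNA1B, PMP22 and GPR17 under all 7 that tested them. KCND2, BNC2 and SOX2 passed under 7 of 8. CACNA1C, PIEZO2, SPRY2 and FN1 passed under 6 of 8, and EBF1 under 6 of 7.

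By list, 4 of 18 synapse genes rose and 0 fell (4 over the list alone), 3 of 7 glia maturation genes rose (5 over the list alone), and 3 of 12 channel genes rose and 1 fell (5 and 1). Of 22 axon guidance genes 3 rose and 4 fell (4 and 5), of 24 subtype transcription factors 3 rose and 1 fell (4 and 1), and of 22 matrix genes 1 rose and 3 fell (1 and 4). RET and endothelin genes gave 2 falls of 12 (1 rise and 4 falls), morphogen genes 2 falls of 24 (2), receptors 2 falls of 13 (3) and stress genes 2 falls of 9 (1 rise and 3 falls). Both measured peptide genes rose, and 1 of 5 inhibitory motor neuron genes rose (2). The cell cycle (26), homeobox (17), epithelium (10), catecholamine (5) and cholinergic (2) lists gave 0 by edgeR, which over all genes gave 1255 at an unadjusted p under 0.05. Over 9834 genes 218 rose and 139 fell, and DESeq2 gave 47 and 17. Set against mesenchyme-like nuclei at E6, edgeR gave 0 higher and 0 lower of 9 glia maturation genes. For synapse genes it gave 1 higher and 0 lower of 21, so most rises of these lists were not shown to be particular to progenitor-like nuclei. Of simulated 2-fold changes of this kind 34.85% were recovered, so not passing does not show that a change was shared. Markers of smooth muscle in progenitor-like nuclei were at 1425 and 1277 CPM at E5 and 615 CPM at E6, those of mesenchyme at 963 and 568 and 451 CPM, and the embryonic haemoglobin gene HBZ, an erythroid marker, fell by 4.29 ± 0.30. At E7, on the other annotation, HES5 rose by 2.31 ± 0.23, ISL1 rose by 3.62 ± 0.27, SCN9A rose by 1.99 ± 0.18, SEMA3D fell by 2.89 ± 0.22 and the FGF-response gene DUSP6 fell by 1.08 ± 0.20, among 1000 rises and 905 falls. SEMA3A and CNTN5 were lower at E6 (-1.51 and -1.79) and higher at E7 (1.60 and 1.76), but without removal of doublet-like nuclei SEMA3A at E7 was -0.028.

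Outside the ENS, the gastrokine GKN2 had 1 and 0 UMIs in epithelium-like nuclei of the E5 libraries, 2244 UMIs (1419 CPM) at E6 and 1155 UMIs at E7; CLDN18, a tight junction gene, had 0 and 0 UMIs at E5, 42 at E6 and 263 at E7, and the trefoil gene TFF3 0, 1, 153 and 167 UMIs. With so few counts at E5 no fold is given. VSIG1 rose by 3.99 ± 0.32, SOX2 by 3.56 ± 0.45 and RUNX1 by 5.39 ± 0.29, while the intestinal factor CDX1 fell by 1.38 ± 0.35 (edgeR, adjusted p = 0.0424). Of 19 homeobox position genes in the epithelium 4 fell, HOXB6 among them (-1.503 ± 0.35), and 6 fell and 1 rose over the list alone. Of 10610 genes, 121 rose and 120 fell (DESeq2 25 and 38, first doublet threshold 233 and 218). In the same nuclei hepatocyte markers summed to 939 and 1012 CPM at E5 and 500 CPM at E6, erythroid markers to 1433 and 870 CPM at E5 and 202 CPM at E6, and pancreas markers to 94.0 and 19.2 CPM at E5 and 156 CPM at E6.

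In smooth muscle-like nuclei, where cluster 1 held 3454 of 3652 and 5118 of 5665 nuclei at E5 and 1086 of 2071 at E6, and cluster 5 held 985 at E6 and 1591 of 1887 at E7, SMOC2 rose at E6 by 2.12 ± 0.17, the retinoic acid receptor RARB by 1.18 ± 0.18 and TNC by 1.04 ± 0.18, while ALDH1A2, which makes retinoic acid, fell by 0.98 ± 0.18. Of 26 cell cycle genes 3 rose at E6 (4 over the list alone) and 15 at E7 (18), with CENPE at 1.57 ± 0.23 and 2.64 ± 0.21. In all 111 genes rose and 39 fell at E6; RLE gave 222 and 138, DESeq2 55 and 62, and no filter 265 and 205. In these nuclei the summed markers of other types also differed: erythroid 2037 and 1122 CPM at E5, 246 CPM at E6 and 454 CPM at E7, mesothelium 343 and 314, 198 and 179 CPM, and mesenchyme 6125 and 5034, 4588 and 4189 CPM. In mesenchyme-like nuclei 39 genes rose and 7 fell at E6 (DESeq2 29 and 18), but this count was not stable: edgeR gave 0 with no filter (912 at an unadjusted p under 0.05), 168 and 65 with doublets kept, 169 and 89 at the first doublet threshold and 246 and 103 at the higher resolution. ALDH1A3 was at 2.10 ± 0.20, THRB, a thyroid hormone receptor, at 2.14 ± 0.21 and HBZ at -4.70 ± 0.47, and each lost the threshold under 1 alternative. At E7 the collagens COL14A1 and COL6A2 rose in mesenchyme-like nuclei by 1.86 ± 0.21 and 1.60 ± 0.18, and the growth factors FGF10 and BMP2 fell by 2.87 ± 0.27 and 1.63 ± 0.22, on the other annotation. Over all nuclei at E6, 236 genes rose and 87 fell of 12126 (RLE 176 and 31, first doublet threshold 97 and 7), with GAL at 2.24 ± 0.24, CHAT at 1.98 ± 0.24 and VIP at 1.11 ± 0.18. Over all nuclei, class shares and levels within classes are not separated. Without the E7 library and on all genes of the NCBI annotation this count was 12.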

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

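The test of class-relative genes against the annotation was chosen after the counts had been seen, and the tests of shared direction and of thinning were written before their results. Age changes were set against those of mesenchyme-like nuclei of the same libraries with an interaction term (edgeR), and differed between classes. Between neuron-like and mesenchyme-like nuclei 250 genes differed in their change at E6 and 518 at E7, and between progenitor-like and mesenchyme-like nuclei 321 and 895. Between neuron-like and progenitor-like nuclei 164 and 368 genes differed, between epithelium-like and mesenchyme-like nuclei 111 and 576, and between smooth muscle-like and mesenchyme-like nuclei 407 and 1348.

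At E6 the change in neuron-like nuclei exceeded that in mesenchyme-like nuclei for DLX5 by 2.45 ± 0.71 on the log2 scale, BNC2 by 2.12 ± 0.23, VIP by 1.70 ± 0.32 and PENK by 1.14 ± 0.27. GAL, which rose in neuron-like nuclei, did not exceed its change in mesenchyme-like nuclei (-0.18 ± 0.31, adjusted p = 0.98). Background was not separated from expression in mesenchyme-like nuclei. Where a gene was low there, as GAL was, this contrast does not decide where its change lay. The change in neuron-like nuclei was below that in mesenchyme-like nuclei for ISL1 (-1.05 ± 0.26), SOX6 (-0.92 ± 0.24), EBF1 (-0.90 ± 0.23) and TBX3 (-0.81 ± 0.22). Among neuron-like subclusters ISL1 and EBF1 were highest in subcluster 7 (1093 ± 187 and 2381 ± 383 CPM). It was 16.3 and 10.2% of neuron-like nuclei at E5 and 6.48% at E6. Class-relative changes were not tested without subcluster 7, so those of ISL1 and EBF1 are not read as changes of neuron-like nuclei in general. PENK, SOX6, EBF1, ISL1 and TBX3 did not pass the threshold within neuron-like nuclei or within mesenchyme-like nuclei. For these 8 genes, GAL left out, adjusted p ran from 4.08e-17 for BNC2 to 0.0309 for DLX5, and each value compares 2 E5 libraries with 1 E6 library.

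Many more genes passed at E7 than at E6 in neuron-like nuclei (748 against 38). Of 734 of the E7 genes measured in both classes, 91.4% changed in the same direction in mesenchyme-like nuclei, which goes with the different annotation of the E7 library as a source, though 80.6% of 36 genes did so at E6, where the annotation was shared. Class-relative genes were 518 at E7 against 250 at E6, but the neuron-like sum was deeper at E7 (2676825 against 1078750 UMIs) and 69.2 against 54.6% of simulated 4-fold class-relative changes were recovered, so these counts do not decide on the annotation. With the E7 sum thinned to the depth of the E6 sum, a median of 900 genes passed over 5 draws (625 to 1110), which argues against depth as the cause. In the same draws the E6 count ran from 46 to 282 although no E6 count was altered, so the number of genes past the threshold is itself unsteady; annotation and age cannot be told apart, because the E7 library alone carries both.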

How the results depend on the processing

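Of the named genes under alternatives, 1291 results held direction and side of the threshold, 268 with an E5 library left out held direction and had no test, 118 held direction and lost the threshold, and 4 changed sign: NOX3 in neuron-like nuclei at E6 without subcluster 7 (-0.11), SEMA3A in progenitor-like nuclei at E7 with doublet-like nuclei kept (-0.028), GFRA1 in mesenchyme-like nuclei at E7 at the higher resolution (-0.30) and HOXB6 between neuron-like and progenitor-like nuclei without subcluster 7 (-0.35). The first and last lay in the nuclei removed, and for the others the cause was not tested. The 268 results kept the same E6 or E7 library, and their genes were chosen with both E5 libraries in the fit. Their direction was thus largely set beforehand and does not show stability. The fits on 1 annotation, on genes seen in every library, at the first doublet threshold and without subcluster 7 were chosen after seeing the data. No paired analysis was possible because E5 and E6 shared only replicate 3 and E5 and E7 only replicate 1 among the libraries with counts, which left 0 residual degrees of freedom.

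Counts of genes moved by more than 1.5 times as follows, and the cause was not tested. Neuron-like at E6 (38): RLE 285, DESeq2 22, no filter 267, doublets kept 139, higher resolution 286, 1 annotation 299, genes seen in every library 77, without subcluster 7 281. Neuron-like at E7 (748): RLE 1296, DESeq2 232, no filter 1273, doublets kept 1443, higher resolution 1303, without subcluster 7 1196, linear trend 157. Progenitor-like at E6 (357): DESeq2 64. Progenitor-like at E7 (1905): DESeq2 395, linear trend 354. Mesenchyme-like at E6 (46): no filter 0 by edgeR (912 at an unadjusted p under 0.05; DESeq2 with the filter 47), doublets kept 233, higher resolution 349, 1 annotation 16, first doublet threshold 258. Mesenchyme-like at E7 (1690): DESeq2 852, linear trend 59. Smooth muscle-like at E6 (150): RLE 360, no filter 470, doublets kept 264, higher resolution 362, first doublet threshold 261. Smooth muscle-like at E7 (2635): DESeq2 1288, linear trend 920. Epithelium-like at E6 (241): DESeq2 63, no filter 382, higher resolution 381, 1 annotation 416, first doublet threshold 451. Epithelium-like at E7 (1761): DESeq2 500, linear trend 325. All nuclei at E6 (323): RLE 207, no filter 151, doublets kept 167, 1 annotation 12, first doublet threshold 104. All nuclei at E7 (2904): DESeq2 1910, linear trend 109.

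ENS-like nuclei at E5 (5.94%) were 7.23% with doublets kept, 6.23% at the higher resolution, 6.24% with 1000 UMIs or more and 6.31% at the first doublet threshold; with doublets kept they were 11.7% at E6 and 16.3% at E7, and the order of the ages held in each. Transmitter genes at 5% in E5 replicate 3 were 22 without thinning, since more UMIs were read. Pairs with 1 sign in every library were 19 without subcluster 7. Of other values without a test, 288 transmitter shares, 74 odds ratios and 44 class shares stayed within their spread, and 111, 8 and 46 did not. Without centring, mesenchyme-like nuclei at E5 went from 26.1 to 2.99%, epithelium-like from 6.47 to 0.39% and unnamed from 23.1 to 69.6%. ENS-like nuclei were 5.86% there. With doublets kept, smooth muscle-like nuclei at E5 went from 30.1 to 6.51%. No gene test was run without centring, and changes relative to mesenchyme-like nuclei were tested in the main setting alone. With each library left out, neuron-like against progenitor-like genes ran from 3529 to 3912 and pairs with 1 sign in every library left from 32 to 39; with 3 libraries chance gives 13.8 to 16.5 such pairs against 6.88 with 4, so this does not show that the pairs were stable. With either E5 library left out no test was left, and of the genes past the threshold all held direction except 1 of 357 at E6 and 2 of 1905 at E7 in progenitor-like nuclei. These genes were chosen with both E5 libraries in the fit, and the lone E6 or E7 library stayed the same. Direction was thus largely set beforehand, and this does not show stability. Of simulated 2-fold changes at E6, 22.7% were recovered in neuron-like, 47.8% in progenitor-like and 34.4% in the deeper mesenchyme-like sums, so recovery did not follow depth alone.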

Other observations

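The first test of posterior HOX genes was chosen after those genes had been seen, and so was its change from 10 to 8 genes; the split test was also chosen afterwards, and the other tests were written before their results. Neuron-like nuclei divided into 10 subclusters, and into 14 at a resolution 2 times as high, so their number depends on the setting. Not every one of the 10 was set apart by transmitter genes. Transmitter and transcription factor levels are given as mean CPM ± SD over libraries or for each library. Leading genes outside the fixed lists may have taken part in clustering, and they only describe a subcluster. Subcluster 2 held NOS1 (241 ± 72.3) with ETV1 (2641 ± 620) and TBX3 (2764 ± 515), CHAT was 1.3 ± 2.6 there, and it made up 13.4 and 15.7% of neuron-like nuclei at E5, 14.9% at E6 and 15.3% at E7. Subcluster 1 held ETV1 (2283 ± 396) and TBX3 (2231 ± 537) with VIP at 68.3 and 113 CPM at E5, 370 at E6 and 1313 at E7, and was 30.4 and 24.6% at E5, 15.5% at E6 and 19.2% at E7. Subcluster 3 held PENK (2574 ± 922), CHAT (729 ± 109) and SLC5A7 (727 ± 209), and was 7.77, 11.8, 11.8 and 15.1%. Subcluster 4 held CHAT (702 ± 95.4) and SLC18A3 (250 ± 92.1) with BNC2 at 1437 and 188 CPM at E5, 6780 at E6 and 6128 at E7, and was 5.30 and 2.24% at E5, 17.5% at E6 and 15.7% at E7. Subcluster 6 held GAL (743, 1394, 3642 and 3017 CPM) with BNC2 (2099, 335, 5948 and 5909 CPM) and DLX5 (96.9, 167, 724 and 524 CPM), and was 7.42, 7.67, 12.2 and 10.2%. In E5 replicate 3 subcluster 4 held 7 nuclei, with ETV1 at 2199 CPM and TBX3 at 1382 CPM, so its profile in that library differed from the others. Subcluster 6 also differed in E5 replicate 3, with ETV1 at 1505 CPM and TBX3 at 2026 CPM, against 449 and 745 CPM at E6.

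Subcluster 10 held SST1 (724 ± 638, n = 2), PENK and VIP in 0 of 283 and 0 of 313 neuron-like nuclei at E5, 17 of 509 at E6 and 11 of 861 at E7. A count of 0 allows a share of up to 1.29 and 1.17% at E5 (exact 95% upper limits). Subcluster 5, led by the Notch ligand DLL1 and SRRM4, was 9.89, 11.8, 11.6 and 11.8%, and subcluster 8, led by cell cycle genes, 5.30, 9.58, 4.32 and 5.69%. Subcluster 9 carried mesenchymal genes and was 4.24, 6.39, 2.36 and 2.67%. Shares of subclusters were not tested between ages.

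Subcluster 7 stood apart, with DBH (379 ± 126), TH (87.7 ± 38.7), ISL1 (1093 ± 187), EBF1 (2381 ± 383) and HOXB6 (1700 ± 225), and was 16.3 and 10.2% of neuron-like nuclei at E5, 6.48% at E6 and 3.02% at E7. GATA2 and TFAP2B were at 643 ± 164 and 1353 ± 556 CPM there, and at 48.8 and 27.3 CPM or less in every other subcluster. A candidate explanation is neurons from ganglia outside the gut wall, and 36.4% of measured sympathetic neuron genes, 4 of 11 (NTRK3, SLC18A2, GCH1 and CYB561), were higher than in the other neuron-like nuclei in all 4 libraries. Of the other members MAB21L1, CHGB and HAND1 had the most counts (851, 330 and 111 UMIs) and were higher in 2, 3 and 1 of 4 libraries. The share is under the bound written beforehand. However, the list left out DBH, TH, ISL1, GATA2 and TFAP2B, which the subcluster held, so a sympathetic source stays open. Summed posterior HOX genes were higher by a mean log2 ratio of 4.54 over the 10 measured genes of a list of 12, a first run that had been read as going with the explanation; without HOXB6 and HOXA9 the value was 3.34 over 8 genes (2.73 to 4.32), and since these genes prompted the idea they do not decide it. For an immature stage of enteric neurons, summed cell cycle genes were at 0.758 of the level in the other neuron-like nuclei (0.651 to 0.882 over 4 libraries), but those held subcluster 8 and an immature neuron need not divide, so this stays open too, and a posterior or other origin within the gut wall was not tested.

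GKN2 and CLDN18 in the E6 epithelium may come from tissue on the stomach side of the dissection. Of 9 measured genes of a stomach and pylorus list of 19 written before the test, 55.6% (5 genes) were higher over all nuclei at E6 than in both E5 libraries, and 0 passed the threshold by edgeR, which over all genes gave 1567 at an unadjusted p under 0.05 (DESeq2 898). All 9 were also seen at E5, and the most abundant at E6, NKX6-3, was at 1.58 ± 0.43 on the log2 scale (adjusted p = 0.0799, 2.63 and 1.27 CPM at E5), so the list left this explanation open. An unnamed cluster led by GATA3, BARX1 and NKX2-5 held 93 and 7 nuclei at E5, 625 at E6 and 269 at E7, and age stays open as the source of these differences. GKN2, CLDN18 and this cluster were above both E5 libraries at E7 too. If the dissection differed, the ENS-like shares and the gene changes at E6 and at E7 would carry it as well.

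For the comparison of neuron-like with progenitor-like sums, 35 splits of the 8 sums into equal groups exist and 32 could be fitted. The real split gave 4252 genes and the highest of the others 0, so 1 of 32 splits gave as many. Classes were formed by clustering these nuclei, which sets the real split apart beforehand, so the test does not bear on whether chance can be excluded.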
